A study of Danio rerio with 18 samples.

How the data were processed

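The series holds 18 RNA-seq libraries of zebrafish larval liver in a design of 2 genotype labels by 2 treatments, with 4 or 5 libraries per group. Ribosomal RNA was removed from total RNA before paired-end sequencing, per the labels' protocols. The authors deposited a count per gene for every library; per the submitters' processing notes reads were checked with FastQC 0.11.5 and trimmed with Trimmomatic 0.36. The aligner, the counting program, the strand setting, the genome build and the gene annotation are not given in the sources used here, so reads on introns, repeats and overlapping genes could not be told apart. No pair of libraries had identical counts (0 pairs).

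Of 32105 gene IDs, 26269 had a symbol in the reference table, and 4301 of these shared it with another ID; named genes took 87.8% of the counts. Genes with too few counts were left out with edgeR's filterByExpr, which kept 17048 genes (99.56% of the counts) and removed 15057. Libraries were scaled with TMM factors, which ranged from 0.762 to 1.16. All 18 libraries entered a fit with a mean per group (edgeR 4.0.16, quasi-likelihood with robust dispersion, R 4.3.3). The common biological coefficient of variation was 0.218 and the median prior degrees of freedom 28.3. Within groups the variance of counts was 3.29 to 23.1 times that of counting alone, so the spread between samples, not the depth, limited precision for abundant genes. The first principal components of the libraries took 25.2%, 11.9% and 5.71% of the variance.

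The comparisons were mutant against control in DMSO and in palbociclib, palbociclib against DMSO in control and in mutant libraries, the interaction, and mutant in palbociclib against control in DMSO, each as a contrast of that fit. A gene was called at a false discovery rate of 0.05 (Benjamini-Hochberg) with no minimum change. Comparisons that share a group are not independent. Their correlations were set against 20 simulated sets of unchanged groups and recomputed with the shared libraries split between the effects. The simulated genes varied independently, without the tissue composition that moves many genes together. The simulated values therefore vary less than those of real unchanged groups would. The share of the mutant effect left in palbociclib was computed on genes picked in part of the DMSO libraries at a log2 change of 1 or more and measured in the rest. uhrf1 and the shares of counts were compared by exact two-sided permutation tests of the difference in means (for uhrf1 of log2 CPM with a pseudocount of 0.5).

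Gene lists for 19 pathways and 12 cell types (736 genes) were written before the data were examined, as were the comparisons, tests, thresholds and the alternatives chosen in advance. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data, adjusted over 28 lists in 5 comparisons. The estimate from 18 libraries holds the shared response to tissue composition, so both results are given. Lists with fewer than 5 measured members were not tested: germline genes (2 measured), vitellogenins (1) and neutrophil markers (4). No tested list had a member without any count in a compared group. Lists for eye and lens, the nervous system and replication histones were added after the data were seen. Their camera tests were adjusted apart, over the added lists alone in the 5 comparisons. A few genes and 1 tested list are not reported here.

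Genes named in the text followed a rule set before the data were examined: in each comparison the 10 largest changes in either direction among called genes with a usable name, a mean of at least 5 CPM in a group and no overlap between groups, the 4 members of each list with the smallest adjusted p, and a fixed set of genes. Of the tested genes, 14872 had a usable name. Where a group held no more than 3 counts for a gene, the ratio of summed counts is given with an exact 95% interval, or as a lower bound where it held 0; these intervals cover counting error only.

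The scripts were tested on simulated data with 200 changed genes per comparison. At log2 changes of 0.5, 1 and 2, 2.99%, 45.7% and 88.9% were recovered for mutant against control in DMSO, 6.78%, 42% and 87.5% in palbociclib, 2.9%, 47% and 76.9% for palbociclib in control, 7.58%, 47.6% and 88.7% in mutant libraries, 2.63%, 14.5% and 77.4% for the interaction and 7.94%, 50% and 84.5% for the last comparison. Small changes were therefore mostly missed, and a gene not called may still have differed. Between 1 and 7 unchanged genes were called in each, and camera found the shifted list each time and called 0 of 27 unchanged lists. The simulated genes varied independently, while list genes in the data did not (estimated correlation 0.692 for muscle genes, mutant against control in DMSO). The simulation therefore does not test false list calls at the preset correlation in these data.

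The alternatives chosen in advance were DESeq2 median-ratio (RLE) and upper-quartile factors, library size alone, DESeq2 1.42.0 and limma-voom with quality weights as tests, no filter, a filter of 1 CPM in at least 4 libraries, a fit of the compared groups alone, a minimum log2 change of 1, the replicate number as a block, genes with a mean CPM of 10 or more, and each library left out in turn. Alternatives added after the data were seen were scaling to the hepatocyte lists, the muscle share of each library as a covariate, thinning of all libraries to 2467926 counts, and leaving out control palbociclib replicates 4 and 5 together. Up to 100 splits of the libraries into other groups of the same sizes were run for each comparison.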

Results

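Total RNA depleted of ribosomal RNA was sequenced from livers dissected out of zebrafish larvae at 120 h after fertilization. The larvae came from crosses between carriers of hi272, an insertion allele of uhrf1, and carried a transgene that labels hepatocytes with a membrane-bound fluorescent protein. uhrf1 encodes a chromatin protein that is needed to copy DNA methylation onto newly replicated strands. From 48 h the larvae were held in 0.5% DMSO, with or without 20 µM palbociclib, an inhibitor of the kinases CDK4 and CDK6 that drive cells from G1 into S phase. Every library pooled livers of larvae that had the same genotype call. Of the 18 libraries, 4 were labelled control and 5 mutant in DMSO, and 4 were labelled control and 5 mutant in palbociclib. Total counts per library ranged from 4141600 to 5199301 and from 2467926 to 3618445 for control and mutant in DMSO, and from 3400255 to 4764175 and from 2863560 to 4056715 for control and mutant in palbociclib. The labels do not say whether pools of a group came from separate clutches, so p-values measure the spread between these pooled-liver samples, which may be partly technical. The design lets 4 pairwise questions be asked: what differs in mutant livers, whether that difference remains under the inhibitor, and what the inhibitor changes in livers of either genotype. A further test, the interaction, asks whether the mutant effect itself differs between the treatments.

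The targeted gene, uhrf1 (ENSDARG00000103409), was not called lower in the libraries labelled mutant in either treatment. In DMSO its level was 37.8 ± 7.5 CPM (counts scaled to TMM-adjusted library sizes; SD, n = 4) in control and 46.5 ± 7.55 (SD, n = 5) in mutant libraries. In palbociclib it was 48.3 ± 7.75 (SD, n = 4) in control and 41 ± 6.82 (SD, n = 5) in mutant libraries. The log2 fold change between mutant and control was 0.29 in DMSO (SE 0.158, exact two-sided permutation p = 0.151) and -0.23 in palbociclib (SE 0.156, exact permutation p = 0.183). edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all genes, gave adjusted p = 0.223 and 0.721 for these values. With scaling by library size alone, the DMSO difference was 0.63 and passed the test (adjusted p = 0.00785), again with the higher level in the libraries labelled mutant. Counts per gene do not show where on the transcript the reads lie, so the level of uhrf1 does not check the genotype labels. Libraries are for that reason named by their labels, and every direction given for libraries labelled mutant rests on those labels. Gene symbols are given as in the reference table, some of them in capitals, and where several genes share a symbol the end of the gene ID follows it (SQLE_079946). Reads of such near-identical copies may have been split between them by the counting, so their levels are less certain.

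The libraries also held RNA of other tissues, in amounts that differed between groups. Muscle genes took 3.58% ± 0.912 of the counts in control and 5.51% ± 0.773 in mutant libraries in DMSO (SD, n = 4 and 5, exact two-sided permutation p = 0.0317). In palbociclib they took 5.27% ± 0.95 and 5.81% ± 0.438 (SD, n = 4 and 5). Skin genes took 0.531%, 0.792%, 0.772% and 0.835% in the same order. Genes of proteins that hepatocytes secrete took 9.32% ± 1.05 in control and 4.53% ± 0.757 in mutant libraries in DMSO (exact permutation p = 0.00794, the smallest that 4 against 5 libraries allow), and 6.6% ± 1.54 and 6.3% ± 1.01 in palbociclib. Adjusted over 76 such tests of 19 shares in the 4 pairwise comparisons, these were 0.105 for muscle and 0.0754 for the hepatocyte genes. Across the 18 libraries, with group means removed, the hepatocyte share fell where the muscle share was higher (Pearson's r = -0.87, Spearman's rho = -0.872, both permutation p = 1e-05, the smallest that the resampling allows, and adjusted p = 1e-05 over 2 such relations). Without the 2 libraries farthest from the median muscle share, r was -0.88. Both are shares of the same total, so a rise of 1 lowers the other. The permutation p does not account for this.

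**Figure D1:**
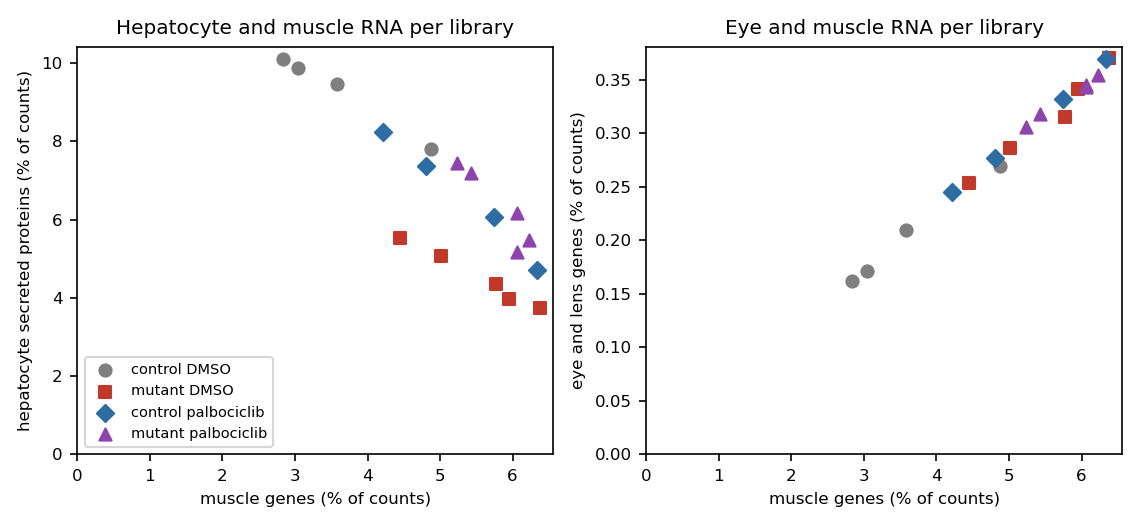
Share of counts in each of the 18 libraries for genes of hepatocyte secreted proteins (left, % of counts) and for eye and lens genes (right, % of counts), against the share of muscle genes (% of counts); each point is a library and its shape and colour give the group. The hepatocyte share was 9.32% on average in control libraries in DMSO and 4.53% in mutant libraries in DMSO, and the eye and lens share followed the muscle share with a within-group Pearson's r of 0.994.

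In DMSO, livers labelled mutant differed from control livers above all by high interferon and inflammatory transcripts and by low hepatocyte transcripts. isg15, a ubiquitin-like protein induced by interferon, was at 326 ± 179 CPM (SD, n = 5) in mutant and 1.16 ± 0.739 (SD, n = 4) in control libraries, a log2 fold change of 8.09 (SE 0.637, adjusted p = 4.11e-07). fabp10a, the fatty acid binding protein of fish hepatocytes, was at 1560 ± 272 CPM against 4810 ± 1070 (log2 fold change -1.62, SE 0.232, adjusted p = 0.000137). Sterol synthesis genes were the lowest group: SQLE_079946, the squalene epoxidase, was at 25.6 ± 6.5 against 233 ± 105 CPM (log2 fold change -3.17, SE 0.393, adjusted p = 3.66e-05). edgeR called 2917 of 17048 genes changed, 1145 higher and 1772 lower in the libraries labelled mutant, at a false discovery rate of 0.05.

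Of 26 measured genes of the interferon response, 19 rose and 1 fell, and 6 were not called. Adjusted over the list alone, 20 rose and 1 fell. The median log2 fold change was 2.76 (camera adjusted p = 1.69e-16; adjusted p = 0.111 with an estimated correlation). Besides isg15, these included b2m and TAP1, which serve antigen presentation by class I molecules, with log2 fold changes of 5.51 (SE 0.605, adjusted p = 1.12e-05) and 3.86 (adjusted p = 1.79e-06). The member that fell was mavs, the adaptor of cytosolic RNA sensors (log2 fold change -0.74, adjusted p = 0.0216), named after its values were seen. Among the 10 largest increases of the named genes were those of class II antigen presentation: the invariant chain cd74a had 989 counts against 1, a ratio of 929 (95% interval 166 to 36700), cd74b had a log2 fold change of 6.52 (adjusted p = 1.35e-06), and mhc2dga, with 120 counts against 0, was at least 37.6-fold higher. The interferon-induced genes mxc (log2 fold change 7.57, adjusted p = 0.000178) and gig2d (ratio 265, 95% interval 47.2 to 10500), the dendritic cell marker cd83 (ratio 205, 95% interval 56.5 to 1700), igldcp (at least 51.4-fold) and the plasminogen activator plaua (ratio 110, 95% interval 19.3 to 4380) were also among the 10 largest increases.

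Of 17 measured inflammatory genes, 15 rose, none fell and 2 were not called. In the list alone, 16 rose after adjustment. The median log2 fold change was 1.92 (camera adjusted p = 5.33e-20; adjusted p = 0.0475 with an estimated correlation). nfkb2, a subunit of the transcription factor NF-kB, was at 73.2 ± 18.1 against 14.7 ± 1.52 CPM (log2 fold change 2.31, SE 0.193, adjusted p = 2.73e-11), its inhibitor nfkbiaa had a log2 fold change of 2.01 (adjusted p = 5.66e-07), and the chemokine ccl19a.1 was at 99.8 ± 42.7 against 1.99 ± 0.961 CPM (log2 fold change 5.64, SE 0.515, adjusted p = 1.77e-06). Leukocyte markers moved apart. Of 13 measured, 3 rose and 1 fell (the same when adjusted over the list alone), and the median was 0.49 (camera adjusted p = 0.00099; adjusted p = 0.133 with an estimated correlation). The 3 that rose were cd74a, cd74b and the protease ctss2.1 (log2 fold change 2.47, adjusted p = 6.22e-05), and the 1 that fell was spi1a, a myeloid transcription factor (log2 fold change -1.33, adjusted p = 0.0174).

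Hepatocyte genes were lower in the libraries labelled mutant, whose muscle share was higher as given above. Of 38 measured genes of secreted proteins, 27 fell, 4 rose and 7 were not called, with the same counts adjusted over the list alone. Their median log2 fold change was -1.62 (camera adjusted p = 2.55e-24; adjusted p = 0.133 with an estimated correlation). The fetuins fetub (log2 fold change -2.12, adjusted p = 6.49e-07) and ahsg1 (log2 fold change -2.87, SE 0.164, adjusted p = 2.05e-16) and the vitamin D carrier GC (log2 fold change -1.80, adjusted p = 9.58e-06) were among them. The 4 that rose, listed after their values were seen, were haptoglobin hp (log2 fold change 3.88), the chemotactic proteins LECT2_090889 and LECT2_033227 (log2 fold changes 5.10 and 2.31) and apoa1a (log2 fold change 0.30). Of 38 measured hepatocyte enzymes, 30 fell and none rose, with the same counts adjusted over the list alone. The enzymes' median was -1.48 (camera adjusted p = 2.05e-29; adjusted p = 0.0734 with an estimated correlation). The liver pyruvate kinase PKLR was at 386 ± 17.7 against 1450 ± 141 CPM (log2 fold change -1.91, SE 0.083, adjusted p = 2.58e-21). Of 24 liver transcription factors, 11 fell and 1 rose (15 and 2 adjusted over the list alone). The median was -0.67 (camera adjusted p = 1.03e-05; adjusted p = 0.279 with an estimated correlation). Among them were the nuclear receptors ESRRA (log2 fold change -1.45, adjusted p = 3.01e-08) and NR1I2 (log2 fold change -1.70, adjusted p = 2.18e-05). The sign of the transcription factor median turned with the muscle share as a covariate (0.15) and with libraries scaled to the hepatocyte genes (0.53).

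Of 25 measured genes of sterol synthesis and uptake, 23 fell and none rose, with the same counts adjusted over the list alone. Their median was -2.12 (camera adjusted p = 2.55e-24; adjusted p = 0.111 with an estimated correlation). The reductase HSD17B7 had a log2 fold change of -1.82 (SE 0.259, adjusted p = 1.27e-06) and the LDL receptor ldlra one of -2.24 (adjusted p = 5.12e-06). Of 24 genes of fatty acid oxidation, 22 fell (24 adjusted over the list alone) and none rose. The median was -1.02 (camera adjusted p = 8.64e-31; adjusted p = 0.0734 with an estimated correlation), and members included the acyl-CoA dehydrogenases ACADVL (log2 fold change -1.02, adjusted p = 1.22e-10) and ACADM (log2 fold change -1.02, adjusted p = 1.64e-10). That median was 0.14 with libraries scaled to the hepatocyte genes. Fatty acid synthesis was mixed: of 19 genes, 8 fell and 3 rose (the same adjusted over the list alone). Their median was -0.34 (camera adjusted p = 0.00526; adjusted p = 0.336 with an estimated correlation), but 0.03 with scaling by library size alone and 0.84 with libraries scaled to the hepatocyte genes. The fatty acid synthase FASN fell (log2 fold change -0.72, SE 0.129, adjusted p = 6.52e-05). The 3 that rose, listed after their values were seen, were the desaturase SCD (log2 fold change 2.97), the elongase ELOVL6 (0.79) and the lipid droplet protein PLIN2 (2.05). The acetyl-CoA synthetase-like gene acss2l, with 9.76 against 191 CPM, had the largest decrease of the named genes (log2 fold change -4.30, SE 0.556, adjusted p = 5.53e-05). The xenobiotic enzyme cyp2ad2 (-3.15) and the vitamin D hydroxylase CYP27B1 (-3.74) were also among the 10 largest decreases.

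Few cell cycle genes were called. Of 33 measured DNA replication genes, 3 rose, none fell and 30 were not called (3 also adjusted over the list alone). Their median was 0.25 (camera adjusted p = 0.0573; adjusted p = 0.392 with an estimated correlation). The 3 were the sliding clamp PCNA, at 129 ± 6.21 against 96.8 ± 9.56 CPM (log2 fold change 0.41, SE 0.106, adjusted p = 0.00394), the helicase subunit MCM4 (0.41, adjusted p = 0.00661) and RPA2 (0.82, adjusted p = 0.0302). Of 29 genes of the G1/S transition, 3 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.0985; adjusted p = 0.279 with an estimated correlation). The cyclins CCND1 (0.23, adjusted p = 0.197) and CCNE2 (-0.12, adjusted p = 0.888) were not called. Of 40 mitosis genes, 4 rose, none when adjusted over the list alone, with a median of 0.39 (camera adjusted p = 0.00167; adjusted p = 0.192 with an estimated correlation). CDK1 was not called (0.17, adjusted p = 0.814). Of 25 genes of the DNA damage response, 4 rose (3 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0719; adjusted p = 0.192 with an estimated correlation), led by the kinase WEE1 (1.62, adjusted p = 8.48e-05). ATR (0.07, adjusted p = 0.91) and CHEK1 (0.41, adjusted p = 0.693) were not called. The replication median was -0.01 with the muscle share as a covariate.

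The death receptor fas (log2 fold change 3.83, SE 0.542, adjusted p = 1.05e-06), casp8, which acts below it (2.58, adjusted p = 2.69e-06), rps27l (2.45, adjusted p = 0.000116) and the ubiquitin ligase mdm2 (46.7 against 20.3 CPM, adjusted p = 9.58e-06) rose. The level of cdkn1a, the p21 inhibitor of cyclin-dependent kinases, was 47.5 against 47.3 CPM (0.01, SE 0.161, adjusted p = 0.987). Of 23 apoptosis genes, 2 rose and 1 fell (the same adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.0497; adjusted p = 0.285 with an estimated correlation).

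Of 23 genes of DNA methylation, 2 fell and none rose, the methyltransferases DNMT3B (-0.64, adjusted p = 0.0117) and DNMT3A_005394 (-0.79, adjusted p = 0.0176), with the same counts adjusted over the list alone (camera adjusted p = 0.455). Scaled by library size alone, neither was called (-0.28, adjusted p = 0.258, and -0.42, adjusted p = 0.187). DNMT1 was not called (0.34, adjusted p = 0.133). Oxidative stress genes went both ways, 3 higher and 7 lower of 18 (the same adjusted over the list alone; camera adjusted p = 0.169), with the quinone reductase NQO1 at 40.5 against 207 CPM (-2.35, adjusted p = 2.75e-07). Of 26 genes of the unfolded protein response, 3 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.728). Of 29 genes of ribosome assembly, 1 rose, none when adjusted over the list alone (camera adjusted p = 0.476). Among other cell types, 18 of 28 muscle genes rose (24 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 9.61e-05; adjusted p = 0.514 with an estimated correlation). So did 4 of 13 skin genes (10 adjusted over the list alone; median 0.26, camera adjusted p = 0.0083; adjusted p = 0.413 with an estimated correlation). Given the muscle share as a covariate, these medians were -0.06 and -0.05. Of 15 stellate cell and fibroblast genes 7 rose (10 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00236; adjusted p = 0.266 with an estimated correlation). Their median was 0.14, with 1 gene called, given the covariate, and their share stayed at 0.119 to 0.134 of the muscle share over the 18 libraries, so the rise went largely with the admixed RNA. Of 13 biliary genes 5 rose and 1 fell (the same adjusted over the list alone), the keratin krt8 among the former (0.60, adjusted p = 1.16e-06; camera adjusted p = 0.169). Biliary genes took 0.281% against 0.164% of the counts (exact permutation p = 0.00794, adjusted p = 0.0754). Of 19 endothelial genes 4 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.227), with the VEGF receptor KDR at a log2 fold change of -1.21 (adjusted p = 0.000342). Of 18 intestinal genes 6 rose and 4 fell (7 and 4 adjusted over the list alone; median 0.20 but mean -0.19, camera adjusted p = 0.742). Of 8 endocrine pancreas genes 3 rose (4 adjusted over the list alone; camera adjusted p = 0.0989). By edgeR none of 9 red cell genes (camera adjusted p = 0.605) and none of 18 exocrine pancreas genes (camera adjusted p = 0.309) was called.

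Of all 17048 genes tested in DMSO, 2399 (14.1%) had no overlap between the libraries of the groups, where chance gives 1.59%. Of the 2917 called, 1981 had none, and 1432 changed at least 2-fold. The share of the calls that were higher, 39.3%, depended on the scaling: it was 50.3% of 3123 calls with upper-quartile factors, 82% of 5708 with library size alone, 97.9% of 13823 with libraries scaled to the hepatocyte genes and 55% of 1153 with the muscle share as a covariate.

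**Figure D2:**
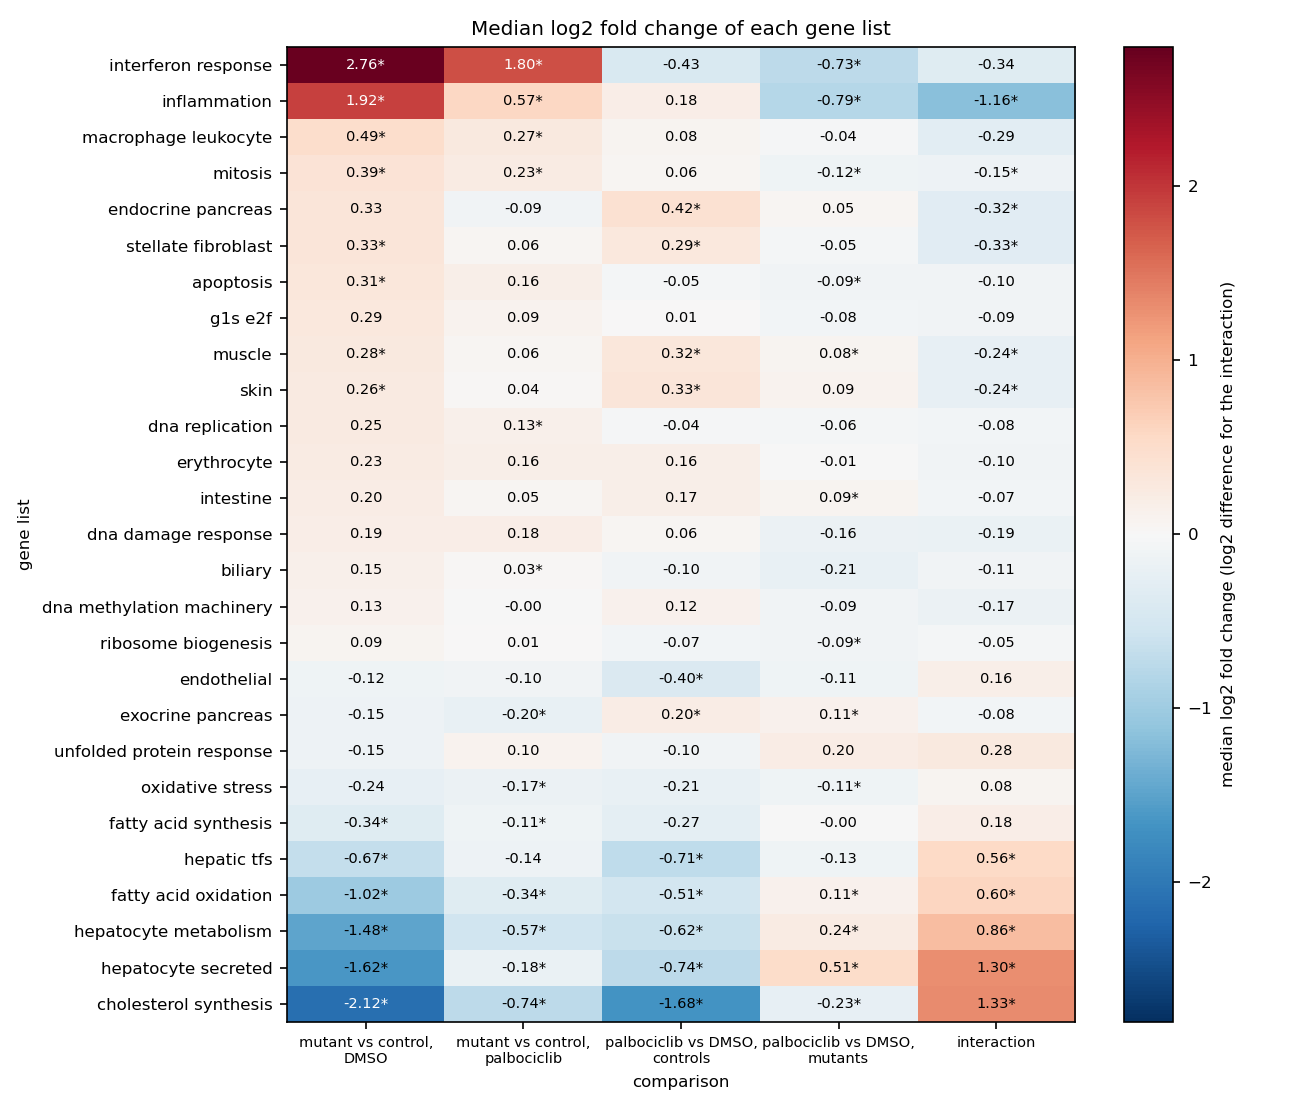
Median log2 fold change (log2 difference for the interaction, colour and number) of 27 gene lists, one per line, in the 5 comparisons, one per column; an asterisk marks a camera adjusted p below 0.05 with the preset correlation. Interferon genes had the highest median in mutant against control in DMSO, 2.76, and sterol synthesis genes the lowest, -2.12; of the 65 tests below that value over all 28 tested lists, 3 passed with an estimated correlation. The sign of some medians near 0, and of the transcription factors, fatty acid genes and muscle genes, turned with another scaling or with the muscle share as a covariate.

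**Figure D3:**
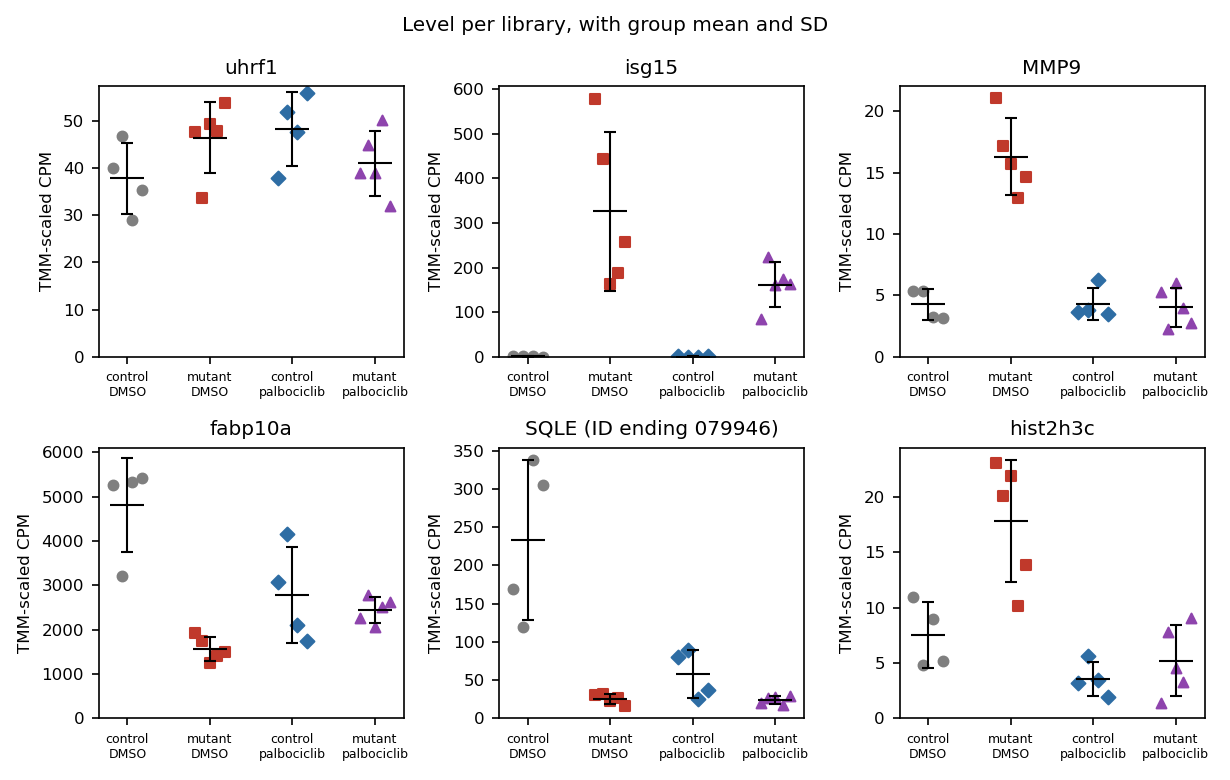
Level of 6 genes in each of the 18 libraries (TMM-scaled CPM, linear axes from 0), with the mean (long bar) and SD (whiskers) of each group. isg15 reached 326 CPM in mutant libraries in DMSO and 161 in palbociclib against 1.16 and 0.699 in control libraries, and MMP9 was at 16.3 CPM in mutant libraries in DMSO and between 4.03 and 4.3 in the other groups.

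Under palbociclib, the libraries labelled mutant again held high interferon transcripts, while far fewer hepatocyte genes were called. isg15 was at 161 ± 50 CPM (SD, n = 5) in mutant and 0.699 ± 0.71 (SD, n = 4) in control libraries (log2 fold change 7.84, SE 0.687, adjusted p = 2.78e-05). ccl19a.1 was at 47.4 against 2.21 CPM (4.41, SE 0.513, adjusted p = 0.000332). fabp10a was at 2450 ± 292 against 2770 ± 1080 CPM and was not called (-0.18, adjusted p = 0.917). edgeR called 179 genes, 108 higher and 71 lower in the libraries labelled mutant.

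Of 26 interferon genes, 6 rose and none fell, and 19 rose adjusted over the list alone. The median was 1.80 (camera adjusted p = 1.39e-29; adjusted p = 0.0475 with an estimated correlation). b2m (5.64, SE 0.663, adjusted p = 0.00035), TAP1 (3.35, adjusted p = 0.000299) and mxc (747 counts against 3, a ratio of 230, 95% interval 78.6 to 1120) were among the 6. cd74a (6.91, adjusted p = 0.000504) and cd74b (4.57, adjusted p = 0.000299) were the 2 leukocyte markers called of 13, with a list median of 0.27 (camera adjusted p = 0.000318; adjusted p = 0.111 with an estimated correlation). Further among the 10 largest increases were gig2d (at least 34.6-fold), rnf213b (ratio 43.5, 95% interval 11.7 to 365), igldcp (ratio 42.1, 95% interval 11.3 to 353) and cfhl5 (4.64, adjusted p = 0.00987). Of 17 inflammatory genes 2 rose, ccl19a.1 and nfkb2 (1.15, adjusted p = 0.000299), and 6 rose adjusted over the list alone (median 0.57, camera adjusted p = 2.96e-10; adjusted p = 0.111 with an estimated correlation). Higher as in DMSO were fas (95 counts against 3, a ratio of 29.3, 95% interval 9.73 to 145), rps27l (2.32, SE 0.355, adjusted p = 0.00339) and casp8 (1.95, adjusted p = 0.00426).

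Of 38 hepatocyte enzymes 2 fell, and 15 adjusted over the list alone (median -0.57, camera adjusted p = 1.38e-14; adjusted p = 0.148 with an estimated correlation). PKLR was at 514 ± 45.1 against 672 ± 80.8 CPM (-0.39, adjusted p = 0.00595). Of 38 secreted protein genes 2 fell and 1 rose, and 4 and 4 adjusted over the list alone. Their median, -0.18 (camera adjusted p = 0.033; adjusted p = 0.698 with an estimated correlation), turned to 0.04 with the muscle share as a covariate and to 0.06 with libraries scaled to the hepatocyte genes. By edgeR none of 25 sterol genes was called over all genes and 9 fell adjusted over the list alone (median -0.74, camera adjusted p = 1.07e-13; adjusted p = 0.196 with an estimated correlation). Of 24 fatty acid oxidation genes 2 fell, and 14 adjusted over the list alone (median -0.34, camera adjusted p = 9.85e-13; adjusted p = 0.192 with an estimated correlation). FASN fell (-0.55, SE 0.129, adjusted p = 0.0212). NQO1 (-1.91, adjusted p = 5.81e-05), CYP27B1 (-1.99, adjusted p = 0.0249) and the xenobiotic enzyme CYP1A1 (1090 against 2930 CPM, -1.43, adjusted p = 0.00987) were among the 10 largest decreases. No gene of the replication, G1/S, mitosis or DNA damage lists was called by edgeR (camera adjusted p = 0.049, 0.169, 0.0315 and 0.53; for replication and mitosis, adjusted p = 0.388 and 0.334 with an estimated correlation). None of the 28 muscle and 13 skin genes was called either (camera adjusted p = 0.34 and 0.604). By edgeR none of 18 exocrine pancreas genes was called over all genes and 2 fell adjusted over the list alone, with 17 below 0 (median -0.20, camera adjusted p = 1.62e-05; adjusted p = 0.334 with an estimated correlation). Of 13 biliary genes 2 rose (4 adjusted over the list alone; median 0.03, camera adjusted p = 0.0255; adjusted p = 0.196 with an estimated correlation). Of 19 fatty acid synthesis genes 1 fell (4 adjusted over the list alone; median -0.11, camera adjusted p = 0.00433; adjusted p = 0.336 with an estimated correlation), with a median of 0.01 when libraries were scaled to the hepatocyte genes. Of 18 oxidative stress genes 1 fell (3 adjusted over the list alone; median -0.17, camera adjusted p = 0.00426; adjusted p = 0.334 with an estimated correlation).

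Of all tested genes 568 (3.33%) did not overlap between the groups, where chance gives 1.59%, and 138 of these were called. An unadjusted p below 0.05 was found for 1656 genes. The count rested on single libraries: it was 318 (116 higher, 202 lower) without control replicate 5, 97 and 96 without control replicates 1 and 2, 115 without mutant replicate 3, and 446 (70 higher, 376 lower) without the control replicates 4 and 5, which held the most muscle RNA of their group. The share higher, 60.3%, was 49.6% of 264 calls with upper-quartile factors and 78.6% of 234 with libraries scaled to the hepatocyte genes. DESeq2 called 328 genes, limma-voom 94, scaling by library size 300, and the fit with the muscle share as a covariate 440.

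The effects of the mutant label in DMSO and in palbociclib, which share no library, were positively correlated across genes, less so by rank. Pearson's r over 17048 genes was 0.601 and Spearman's rho 0.337. The mean r of 20 simulated sets of unchanged groups, with genes that varied independently, was -0.003. Real genes are not independent replicates. What tissue composition, which differed between groups as given above, adds to r was not tested. Of the 108 genes higher in palbociclib, 100 were higher in DMSO too, where independent lists would share 7.25, and of the 71 lower, 65 were lower in DMSO (7.38 by chance); none went the opposite way. For genes chosen in some of the DMSO libraries and measured in the others, the mutant effect in palbociclib was a median of 0.34 of that in DMSO (SD 0.025 over 60 splits of the libraries). All splits used the same palbociclib libraries and overlapping parts of the DMSO libraries, so this SD is not the uncertainty of the ratio. The ratio was not computed with palbociclib libraries left out or with the muscle share as a covariate. A ratio below 1 can come from changes in control libraries as well as in mutant libraries. Among the 297 genes with a positive interaction, given below, the median log2 fold change with palbociclib was -0.862 in control and 0.313 in mutant libraries. Among the 43 negative ones it was 0.61 and -0.861. The muscle share of control libraries was 3.58% in DMSO and 5.27% in palbociclib. The ratio was 0.609 for genes that were higher and 0.3 for genes that were lower.

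In livers labelled control, palbociclib was accompanied by lower levels of most sterol and fatty acid oxidation genes, in a comparison for which chance is not excluded. Of the 35 splits of these 8 libraries, 2, the real one included, reached the real count (highest other 1647). No gene list passed with an estimated correlation. SQLE_079946 was at 57.6 ± 31.3 CPM (SD, n = 4) in palbociclib against 233 ± 105 (SD, n = 4) in DMSO (log2 fold change -2.02, SE 0.398, adjusted p = 0.0104). PKLR was at 672 ± 80.8 against 1450 ± 141 CPM (-1.11, SE 0.0874, adjusted p = 7.94e-12). The replication gene PCNA had a log2 fold change of 0.01 (adjusted p = 0.98). edgeR called 973 genes, 235 higher and 738 lower.

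Of 25 sterol genes 19 fell and none rose, and 23 fell adjusted over the list alone (median -1.68, camera adjusted p = 1.83e-24; adjusted p = 0.111 with an estimated correlation). The genes HSD17B7 (-1.75, adjusted p = 0.000161) and the mevalonate kinase MVK (-1.88, adjusted p = 0.000826) had the smallest p. Of 24 fatty acid oxidation genes 17 fell, and 20 adjusted over the list alone (median -0.51, camera adjusted p = 9.18e-16; adjusted p = 0.148 with an estimated correlation), such as ACADM (-0.61, adjusted p = 0.00028). Of 24 liver transcription factors 8 fell, and 15 adjusted over the list alone (median -0.71, camera adjusted p = 1e-07; adjusted p = 0.196 with an estimated correlation), led by the nuclear receptor NR5A2 (-1.26, adjusted p = 0.00231). Of 38 secreted protein genes 7 fell and 2 rose, and 21 and 2 adjusted over the list alone (median -0.74, camera adjusted p = 2.31e-12; adjusted p = 0.27 with an estimated correlation). Called were GC (-1.54, adjusted p = 0.00115) on the lower side and hp (3.30, adjusted p = 0.0108) on the higher. Of 38 hepatocyte enzymes 5 fell, and 18 adjusted over the list alone (median -0.62, camera adjusted p = 1.94e-11; adjusted p = 0.192 with an estimated correlation). acss2l (26.6 against 191 CPM, -2.86, SE 0.541, adjusted p = 0.00836) and the apolipoprotein B gene apobb.2 (43.9 against 252 CPM, -2.51, adjusted p = 0.00231) had the largest decreases of the named genes.

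The muscle share was 5.27% against 3.58% in these groups, and 18 of 28 muscle genes (23 adjusted over the list alone; median 0.32, camera adjusted p = 1.5e-10; adjusted p = 0.332 with an estimated correlation) rose. Of 13 skin genes 3 rose (11 adjusted over the list alone; median 0.33, camera adjusted p = 4.78e-06; adjusted p = 0.196 with an estimated correlation). All 18 exocrine and all 8 endocrine pancreas genes lay above 0, and 1 of each rose, CEL_029822 and NEUROD1 (1 of each adjusted over the list alone). For the exocrine list the median was 0.20 (camera adjusted p = 0.000182; adjusted p = 0.385 with an estimated correlation), and -0.04 with the muscle share as a covariate. For the endocrine list it was 0.42 (camera adjusted p = 0.0083; adjusted p = 0.192 with an estimated correlation). Of 15 stellate cell and fibroblast genes 3 rose (7 adjusted over the list alone; median 0.29, and 0.02 with the muscle share as a covariate; camera adjusted p = 0.00426; adjusted p = 0.28 with an estimated correlation). Of 19 endothelial genes 2 fell (4 adjusted over the list alone; median -0.40, camera adjusted p = 0.00707; adjusted p = 0.108 with an estimated correlation), as in TIE1 (-0.94, adjusted p = 0.00923). Among genes that met the naming rule for large changes, the axonemal dynein DNAH5 had the largest increase, at 19.7 ± 15 against 3.14 CPM (2.63, SE 0.476, adjusted p = 0.00175). The neuronal calcium channel cacna1eb followed (1.87, adjusted p = 0.0308). The increase of hp, named above as a list member, was larger (3.3). By edgeR no gene of the replication, G1/S, mitosis, DNA damage, interferon and inflammation lists was called (camera adjusted p = 0.672, 0.58 and 0.34 for the cell cycle lists and 0.381 and 0.0706 for the last 2), while 3494 genes of 17048 had an unadjusted p below 0.05.

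This comparison was the least firm of the 4. Of all tested genes 1606 (9.42%) did not overlap between the groups, where chance gives 2.86%, and 605 of these were called. With the muscle share as a covariate 45 genes were called (29 higher, 16 lower), none of them sterol or fatty acid oxidation genes; the sterol median was then -0.49 and that of secreted protein genes 0.02. Without the control palbociclib replicates 4 and 5, the libraries of that group with the most muscle RNA, 34 genes were called; without replicate 4 or 5 alone, 338 and 304; and without the control DMSO replicates 2, 3 and 4 in turn, 2019, 311 and 272. A fit of these groups alone called 351. The share higher, 24.2%, was 42.4% of 1047 calls with upper-quartile factors, 73.3% of 1472 with library size alone and 97.8% of 4472 with libraries scaled to the hepatocyte genes, with which the fatty acid oxidation median was 0.10.

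In livers labelled mutant, palbociclib was accompanied by lower inflammatory genes, and few hepatocyte genes were called. The matrix metalloproteinase MMP9 was at 4.03 ± 1.6 CPM (SD, n = 5) in palbociclib and 16.3 ± 3.12 (SD, n = 5) in DMSO (log2 fold change -2.00, SE 0.3, adjusted p = 0.000124), close to the 4.27 ± 1.26 of control libraries in DMSO. irg1l, an itaconate-producing enzyme gene, was at 1.36 ± 1.01 against 12.3 ± 3.75 CPM (-3.14, SE 0.441, adjusted p = 8.36e-05). PKLR was at 514 ± 45.1 against 386 ± 17.7 CPM (0.41, SE 0.078, adjusted p = 0.00376). edgeR called 92 genes, 7 higher and 85 lower.

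Of 17 inflammatory genes 5 fell and none rose, and 11 fell adjusted over the list alone (median -0.79, camera adjusted p = 1.13e-20; adjusted p = 0.0475 with an estimated correlation): irg1l, MMP9, mmp13a (-2.37, adjusted p = 0.0199), nfkb2 (-0.68, SE 0.164, adjusted p = 0.0405) and the AP-1 subunit JUNB_104773 (-1.01, adjusted p = 0.0131). plaua (-3.36, SE 0.586, adjusted p = 0.00147), the collagen receptor subunits itga2.1 (-3.22, adjusted p = 0.00625) and itga2.3 (-2.15, adjusted p = 0.00952) and ACOD1, of the same enzyme family as irg1l (-2.11, adjusted p = 0.00335), were further named decreases. By edgeR none of 26 interferon genes was called over all genes and 3 fell adjusted over the list alone (median -0.73, camera adjusted p = 6.35e-10; adjusted p = 0.192 with an estimated correlation). isg15 was at -1.02 (SE 0.355, adjusted p = 0.379). The histone variant h2ax fell (-1.12, SE 0.219, adjusted p = 0.00538), the 1 called of 25 DNA damage genes (2 adjusted over the list alone; camera adjusted p = 0.115).

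Of 38 secreted protein genes 1 rose (also adjusted over the list alone), ahsg1 (0.76, SE 0.164, adjusted p = 0.0128), and 34 lay above 0 (median 0.51, camera adjusted p = 8.03e-15; adjusted p = 0.211 with an estimated correlation). Of 38 hepatocyte enzymes PKLR alone rose (2 adjusted over the list alone; median 0.24, camera adjusted p = 1.62e-05; adjusted p = 0.336 with an estimated correlation), with a median of -0.09 when libraries were scaled to the hepatocyte genes. The other named increases were the lactate dehydrogenase ldhbb (1.00, adjusted p = 0.0243), the coagulation factor F7_075827 (0.82, adjusted p = 0.00722) and ALDH7A1 (0.42, adjusted p = 0.0205). None of 25 sterol genes was called, and their median was -0.23 (camera adjusted p = 0.0221; adjusted p = 0.656 with an estimated correlation). No gene of the replication, G1/S and mitosis lists was called by edgeR (camera adjusted p = 0.369, 0.377 and 0.0272; for mitosis adjusted p = 0.334 with an estimated correlation). Nor was any of 28 muscle genes (median 0.08, camera adjusted p = 0.0311; adjusted p = 0.698 with an estimated correlation), the muscle share being 5.81% against 5.51%. Lists with smaller medians also passed with the preset correlation: exocrine pancreas (0.11, camera adjusted p = 0.00426; adjusted p = 0.506 with an estimated correlation), fatty acid oxidation (0.11, camera adjusted p = 0.000843; adjusted p = 0.499 with an estimated correlation), intestine (0.09, camera adjusted p = 0.0274; adjusted p = 0.336 with an estimated correlation), apoptosis (-0.09, camera adjusted p = 0.0221; adjusted p = 0.209 with an estimated correlation), oxidative stress (-0.11, camera adjusted p = 0.0315; adjusted p = 0.452 with an estimated correlation) and ribosome assembly (-0.09, camera adjusted p = 0.0497; adjusted p = 0.413 with an estimated correlation). Of their genes only gpx1b of the oxidative stress list was called, lower, and 1 oxidative stress and 1 apoptosis gene fell adjusted over the list alone. The first 3 had medians below 0 when libraries were scaled to the hepatocyte genes. Over all genes 1502 had an unadjusted p below 0.05.

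Of all tested genes 391 (2.29%) did not overlap between the groups, where chance gives 0.794%, and 79 of these were called. The count was 39 and 56 without mutant DMSO replicates 1 and 2, and 52 and 61 without mutant palbociclib replicates 1 and 4. With the muscle share as a covariate it was 367 (56.7% higher against 7.61%), with library size alone 141 (25.5% higher), with libraries scaled to the hepatocyte genes 427, and in a fit of these groups alone 181 (37% higher). The effects of palbociclib in control and mutant libraries, which share no library, had a weak correlation across genes (Pearson's r = 0.073, Spearman's rho = 0.0766). The r of 20 simulated sets of unchanged groups was -0.0151 to 0.0156. Their genes varied independently, without differences in tissue composition, so this range does not exclude chance. With each library left out in turn r was 0.0123 to 0.102. In both control and mutant libraries 7 genes were lower, where independent lists would share 3.68. A further 5 genes were lower in control and higher in mutant libraries (0.303 by chance). r was -0.04 over the 9585 genes with a mean CPM of 10 or more. Against the mutant effect in DMSO, 77 of the 85 genes lower with palbociclib had been higher in the libraries labelled mutant and all 7 that were higher had been lower, in comparisons that share the mutant DMSO libraries. Across genes r was -0.448, but the mutant DMSO libraries enter both effects with opposite sign, and simulated unchanged groups gave -0.479. The covariance was -0.137 against -0.0513 simulated with genes that varied independently. When the mutant DMSO libraries were split so that none entered both effects, r was -0.252 (median of 10 splits, -0.289 to -0.148).

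The interaction tested whether the mutant effect differed between palbociclib and DMSO. edgeR called 340 genes, 297 with a positive and 43 with a negative difference, at 2273 genes with an unadjusted p below 0.05. Of the 297 positive ones, 295 were also lower in DMSO in the libraries labelled mutant and 265 were lower in control libraries with palbociclib than with DMSO. Both contrasts are parts of the interaction and share the control DMSO libraries with it, so such overlap follows in part from how the genes were chosen, by an amount that was not tested. Called higher with palbociclib in mutant libraries were 5 of the 297. Of the 43 negative ones, 41 were higher in DMSO in the libraries labelled mutant and 18 fell with palbociclib there, under the same limit.

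Of 38 secreted protein genes 7 had a positive and 1 a negative difference, and 28 and 2 adjusted over the list alone (median 1.3, camera adjusted p = 2.85e-26; adjusted p = 0.111 with an estimated correlation). These included fetub (1.44, adjusted p = 0.00672), ahsg1 (1.84, SE 0.228, adjusted p = 5.32e-06) and fabp10a (1.44, SE 0.328, adjusted p = 0.0384). Of 38 hepatocyte enzymes 4 were positive, and 17 adjusted over the list alone (median 0.86, camera adjusted p = 5.27e-17; adjusted p = 0.111 with an estimated correlation), PKLR at 1.52 (SE 0.117, adjusted p = 3.57e-12). Of 24 fatty acid oxidation genes 12 were positive, and 18 adjusted over the list alone (median 0.60, camera adjusted p = 5.61e-19; adjusted p = 0.111 with an estimated correlation). Of 24 transcription factors 3 were, and 5 adjusted over the list alone (median 0.56, camera adjusted p = 0.00017; adjusted p = 0.334 with an estimated correlation). By edgeR none of 25 sterol genes was called and 17 were positive adjusted over the list alone (median 1.33, camera adjusted p = 5.1e-13; adjusted p = 0.196 with an estimated correlation). With libraries scaled to the hepatocyte genes the medians of enzymes, fatty acid oxidation and transcription factors were -0.04, -0.36 and -0.34. With the muscle share as a covariate that of the transcription factors was -0.03. The largest positive difference was that of apobb.2, at 252, 34, 43.9 and 65.5 CPM in control and mutant libraries in DMSO and control and mutant libraries in palbociclib (3.44, SE 0.521, adjusted p = 0.00333). The carboxylesterase ces3 was at 225, 21.7, 55.1 and 45 CPM (3.08, SE 0.327, adjusted p = 7.94e-05).

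Of 17 inflammatory genes 5 had a negative and none a positive difference, and 9 adjusted over the list alone (median -1.16, camera adjusted p = 1.65e-11; adjusted p = 0.108 with an estimated correlation): mmp13a (-4.18, SE 0.857, adjusted p = 0.00493), MMP9 (-2.02, adjusted p = 0.0113), nfkb2 (-1.16, adjusted p = 0.0115), nfkbiaa (-1.44, adjusted p = 0.0367) and JUNB_104773 (-1.19, adjusted p = 0.0425). By edgeR none of 26 interferon genes was called (median -0.34, camera adjusted p = 0.0585). None of 28 muscle genes was called, with a median of -0.24 (camera adjusted p = 9.84e-05; adjusted p = 0.514 with an estimated correlation) that was 0.03 with the muscle share as a covariate, and none of 15 stellate cell and fibroblast genes (median -0.33, camera adjusted p = 0.00151; adjusted p = 0.236 with an estimated correlation). The lists of endocrine pancreas (-0.32, camera adjusted p = 0.0175; adjusted p = 0.2 with an estimated correlation), mitosis (-0.15, camera adjusted p = 0.0315; adjusted p = 0.334 with an estimated correlation) and skin (-0.24, camera adjusted p = 0.00597; adjusted p = 0.392 with an estimated correlation) had negative medians as well. None of their genes was called by edgeR, and 3 endocrine genes were negative adjusted over the list alone. The medians of mitosis and skin were 0.01 and 0.04 with the muscle share as a covariate. The interaction count was 842 without control DMSO replicate 2, 172 and 168 without replicates 3 and 4 of that group, 219 and 218 without mutant DMSO replicates 3 and 4, 538, 188 and 218 without control palbociclib replicates 2, 4 and 5. It was 88 without the last 2 together. The share positive, 87.4%, was 63.4% of 391 calls with library size alone, 0.899% of 7453 with libraries scaled to the hepatocyte genes and 60% of 190 with the muscle share as a covariate, and DESeq2 called 605 genes.

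**Figure D4:**
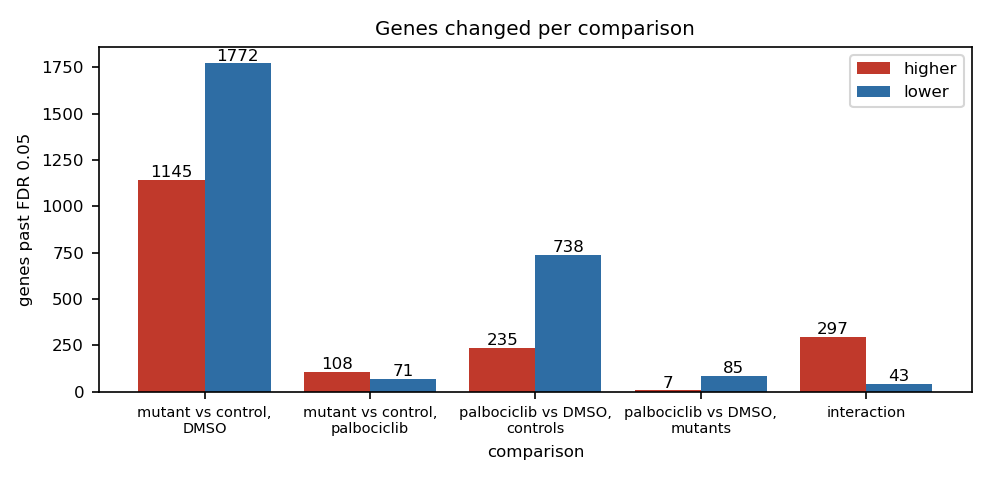
Number of genes past a false discovery rate of 0.05 in edgeR (axis from 0) in 5 comparisons, higher and lower in the group or treatment named first; for the interaction, positive and negative differences. The mutant label in DMSO gave 1145 higher and 1772 lower genes, against 108 and 71 in palbociclib, and palbociclib gave 235 and 738 in control and 7 and 85 in mutant libraries.

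Mutant libraries in palbociclib still differed widely from control libraries in DMSO. edgeR called 2825 genes, 1062 higher and 1763 lower, and 1137 of them changed at least 2-fold. Of these, 582 higher and 1414 lower genes were called in the same direction for mutant against control in DMSO, a comparison with the same control libraries, which by itself makes calls coincide. isg15, fabp10a and SQLE_079946 stood at 161, 2450 and 23.8 CPM against 1.16, 4810 and 233. Of all tested genes 2294 (13.5%) did not overlap between the groups, where chance gives 1.59%, and 1814 of these were called. Without control DMSO replicate 4, 1862 genes were called. With the muscle share as a covariate 482 genes were called, and the share higher, 37.6%, was 48.3% of 3018 calls with upper-quartile factors, 81% of 5276 with library size alone, 96.3% of 9951 with libraries scaled to the hepatocyte genes and 62% with the covariate. The effect of the mutant label in DMSO and that of palbociclib in control libraries, which share the control DMSO libraries, had 633 lower genes and 163 higher genes in common. Their correlation across genes was 0.537, against 0.52 for simulated unchanged groups. The covariance was 0.208 against 0.0609 simulated with genes that varied independently. When the control libraries were split between the effects, the correlation was 0.379 (median of 6 splits, 0.27 to 0.386).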

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

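The tests of the weighed patterns (dilution of hepatocyte genes, muscle share, library size, leukocytes, mislabelling and the eye and muscle ratio) were chosen only after the results were seen; the interaction and the splits of the libraries were planned.

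Samples far from the rest of their group were found in 23 of 412 groups (103 measures, 86 of them genes), and chance gives about 1 in 20. Control DMSO replicate 2 had 4141600 counts (others 5066810 to 5199301), 19.6% of them in the 10 most abundant genes (others 24.8% to 25.5%), fabp10a at 3210 CPM (5270 to 5420), fas at 2.19 CPM (0.249 to 0.468), cyp1c2 at 3.4 CPM (1.56 to 1.74) and mmp13a at 0 CPM (0.995 to 1.17). It also held the most muscle RNA of its group, 4.87%. Against 0 in the other libraries of their group, cd74a was at 0.234 CPM in control DMSO replicate 1, gig2d at 0.249 and cd83 at 0.498 in replicate 3, plaua at 0.26 in replicate 4 and igldcp at 0.632 in control palbociclib replicate 2. These were 1 count each for cd74a, gig2d and plaua and 2 each for cd83 and igldcp. Where all other libraries of a group hold 0, any count is flagged. ATR was at 9.87 CPM in control DMSO replicate 4 (others 6.72 to 7.02). In control palbociclib libraries, rnf144b was at 6.66 CPM (10.3 to 10.8) and b2m at 2.15 CPM (0.201 to 0.316) in replicate 1, and MMP9 at 6.24 CPM (3.51 to 3.79) in replicate 4. In mutant DMSO libraries, h3c13a was at 19.7 CPM in replicate 1 (5.95 to 8.47), PMVK at 5.21 in replicate 4 (0.541 to 1.75) and lingo4b at 11.2 in replicate 5 (2.44 to 4.36). In mutant palbociclib libraries, MSMO1 was at 51.6 CPM (44.4 to 45.9) and ldhbb at 126 CPM (94.6 to 103) in replicate 2, VDR_070721 at 15.3 CPM (22 to 24.5) and cbln13 at 12.6 CPM (5.85 to 7.25) in replicate 4, and CHEK1 at 5.74 CPM (1.67 to 2.65) in replicate 5.

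The mutant effect differed between palbociclib and DMSO, by the interaction test, for 340 genes. The named ones were apobb.2 (3.44), cbln9 (3.09), ces3 (3.08), UNC93B1 (2.96), AVPR1A_045788 (2.8), IGFALS (2.70), COMTD1 (2.63), ticam1 (2.58), cbln13 (2.54) and VGLL4_094332 (2.5) with positive, and mmp13a (-4.18), cd83 (-3.86), ACOD1 (-3.44), hs3st1l2 (-2.73), lingo4b (-2.60), cyp1c2 (-2.36), MMP9 (-2.02), PRDM1 (-1.87), kcnb2a (-1.72) and GAB2 (-1.70) with negative log2 differences. Among lists, the median differences of hepatocyte secreted proteins (1.3), hepatocyte enzymes (0.86), liver transcription factors (0.56), sterol synthesis (1.33) and fatty acid oxidation (0.60) were positive. Those of mitosis (-0.15), inflammation (-1.16), stellate cells and fibroblasts (-0.33), endocrine pancreas (-0.32), muscle (-0.24) and skin (-0.24) were negative. All 11 passed camera with the preset correlation and none with an estimated one.

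Other splits of the libraries show where chance can be excluded. For mutant against control in DMSO the real split alone, 1 of 100, reached its count (2917, highest other 1663), and the same held in palbociclib (179, highest other 12), for palbociclib in mutant libraries (92, highest other 3) and for mutant in palbociclib against control in DMSO (2825, highest other 1661). For the interaction 2 of 100 splits, the real one included, reached the real count (340, highest other 720). They were taken from 8820 possible splits and exchanged treatment labels within each genotype. Such splits assume no effect of palbociclib in either genotype, so they cannot exclude chance for the interaction itself. For palbociclib in control libraries 2 of 35 splits, the real one included, reached the real count (973, highest other 1647), and chance is not excluded.

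Hepatocyte genes were lower in mutant than in control libraries in DMSO, with a median log2 fold change of -1.48 over 125 members of the hepatocyte, sterol and fatty acid oxidation lists, 102 of them called lower. With libraries scaled to the hepatocyte lists 77 members were past the threshold, 23 higher and 54 lower. Most of those higher were not called higher before, when only 4 secreted protein genes and no member of the other lists were. That excludes an equal dilution of all members as the whole cause. It does not exclude an unequal dilution, since members that the admixed RNA also holds would be diluted less. Library size is excluded, since 100 of the 102 were still called lower after thinning. With the muscle share as a covariate the median was -0.692 and 61 of the 102 calls held (median SE 0.255 before and 0.22 after), so a part that goes with the admixed RNA cannot be told apart from the effect of the mutant label, because the muscle share differed between the groups. A lower content of hepatocytes and lower expression per hepatocyte stay open, and were not separated.

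Interferon genes were higher in the libraries labelled mutant, with a median log2 fold change of 2.76 in DMSO. Leukocyte markers as a set did not rise by that size. Their median log2 fold change was 0.437 without cd74a and cd74b (SD 0.936, range -1.33 to 2.47, 1 of 11 called higher). It was 0.49 over all 13 markers, 3 of them called higher. The 2 genes were left out after their values were seen. Medians of markers do not test higher expression within leukocytes, so leukocytes are not excluded as a source. A smaller rise of leukocytes stays open too. The share of leukocyte genes, cd74a and cd74b included, was 0.023% against 0.0103% and that of neutrophil genes 0.00538% against 0.00254% (both exact permutation p = 0.00794, adjusted p = 0.0754). In DMSO the lowest mean log2 CPM of 26 interferon genes in a library labelled mutant lay 1.52 above the highest in one labelled control. That is more than 2 times the largest SD within a group (0.552). It argues against single libraries exchanged between control and mutant labels in DMSO only if interferon levels follow the genotype. That link was not checked apart from the labels, so such an exchange is not excluded. In palbociclib such an exchange cannot be told apart, since that distance was 0.556 and the largest SD 0.624, although no library lay out of place and isg15 alone was at 83.7 CPM or more against 1.99 or less over all libraries. Interferon genes chosen in the other treatment (19 and 20 genes) gave 2.04 (largest SD 0.671) in DMSO and 0.732 (0.76) in palbociclib. The test was first made over both treatments together, where the distance was 0.445, and was split by treatment after that was seen. An exchange of whole groups or of treatment labels was not tested, and an interferon response that goes with the mutant genotype stays open too.

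Eye, lens, nerve and muscle RNA was present in every library. Organs next to the liver taken along with it are excluded as its source, since the eye and lens share over the muscle share varied by only 1.93% (coefficient of variation, ratio 0.0546 to 0.0586), while the same value was 14.8% for exocrine pancreas and 21.1% for intestine genes. A common source of RNA from the whole body in every library fits, with a within-group Pearson's r of 0.994 between the eye and lens share and the muscle share. RNA of whole larvae carried into the samples, or reads exchanged with libraries of whole larvae during sequencing, could each give that, and the data at hand do not separate them. No biological explanation was tested.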

How the results depend on the processing

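Scaling to the hepatocyte lists, the muscle covariate, thinning, and leaving out control palbociclib replicates 4 and 5 together were chosen only after the results were seen; the other alternatives were planned.

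Counts of changed genes kept within 1.5 times their value with RLE factors, with upper-quartile factors, with either other filter and after thinning in all comparisons. With library size alone they were 5708 for mutant against control in DMSO (from 2917), 300 in palbociclib (from 179), 1472 for palbociclib in control (from 973) and 141 in mutant libraries (from 92), and 5276 for mutant in palbociclib against control in DMSO (from 2825). The median log2 fold change of all genes was then 0.418, 0.117, 0.234, -0.0113 and 0.391, and -0.268 for the interaction, where 391 genes were called (63.4% positive). With libraries scaled to the hepatocyte lists the counts were 13823, 4472 for palbociclib in control, 427 in mutant libraries, 7453 for the interaction and 9951 for the last comparison. That scaling assumes that hepatocyte genes do not change on average, and the median of all genes was then 1.21, 0.603, -0.357, -0.984 and 0.84, so its own construction gives these counts. For mutant against control in palbociclib it was 0.196. With upper-quartile factors that median was 0.131 for mutant against control in DMSO and 0.115 for the last comparison.

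With the muscle share as a covariate the counts were 1153, 440, 45, 367, 190 and 482 in the order DMSO, palbociclib, control, mutant, interaction and last comparison. Without control palbociclib replicates 4 and 5 they were 446 for mutant against control in palbociclib, 34 for palbociclib in control libraries and 88 for the interaction. A fit of the compared groups alone gave 351 for palbociclib in control and 181 in mutant libraries. DESeq2 called 328 genes in palbociclib and 605 for the interaction, and limma-voom 94 in palbociclib. A minimum log2 change of 1 left 1432, 278 and 1137 genes for mutant against control in DMSO, palbociclib in control libraries and the last comparison, by its construction. For the others the cause was not tested.

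With the replicate number as a block, 111 genes were called for mutant against control in palbociclib, 264 and 59 for palbociclib in control and mutant libraries and 134 for the interaction; the block takes degrees of freedom from the fit. Nothing in the labels says that numbers pair libraries. Over 24 pairs of libraries with the same number the correlation of residuals was -0.19 to 0.057, none above 0.1, and 1 of 18 libraries was closest to a library with its own number, so no pairing was used.

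Leaving out each library in turn gave 2094 to 3456 genes for mutant against control in DMSO, 96 to 318 in palbociclib, 272 to 2019 for palbociclib in control and 39 to 103 in mutant libraries, 168 to 842 for the interaction and 1862 to 3526 for the last comparison. The cause was not tested. The log2 fold change of uhrf1 in DMSO was 0.19 to 0.41, the agreement of the mutant effects 0.55 to 0.603, that of the palbociclib effects 0.0123 to 0.102 and the opposition -0.469 to -0.406. Between 55 and 71 of 140 list tests passed. The test of the list hepatocyte_secreted, mutant vs control in palbociclib, reversed without control palbociclib replicate 2 (adjusted p = 0.984) and had adjusted p = 1.96e-06 without replicate 5; the cause was not tested.

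The direction of uhrf1 in DMSO held with the other scalings (RLE, upper quartile and library size), with the block and with each library left out, the alternatives run for it, and it passed the test with library size alone (0.63). With genes of a mean CPM of 10 or more the agreement of the mutant effects was 0.676, and that of the palbociclib effects turned to -0.0405 (from 0.0726); the cause was not tested. With correlations estimated from the data 3 of the 65 list tests passed. Of 353 values of named genes, 349 kept their call with RLE factors, 348 with upper-quartile factors, 319 with library size alone and 262 with the block, and none turned. Depth limits genes of few counts: the lowest total was 2467926, and 100 of 102 hepatocyte calls held after thinning to it.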

Other observations

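All tests in this part were chosen only after the results were seen.

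Replication histones, whose transcripts are made in S phase and mostly lack a poly(A) tail, were seen in these libraries of total RNA. All 12 measured genes lay above 0 for mutant against control in DMSO (median log2 fold change 1.23, 6 called higher, camera adjusted p = 8.4e-05; adjusted p = 0.053 with an estimated correlation) and in palbociclib (median 0.88, none called, adjusted p = 0.00011; 0.053 with an estimated correlation). With palbociclib 11 of 12 lay below 0 in mutant libraries (median -1.52, 4 called lower, adjusted p = 7.28e-16; 0.000463 with an estimated correlation) and 10 of 12 in control libraries (median -1.16, 1 called lower, adjusted p = 0.00292; 0.123 with an estimated correlation). The interaction median was -0.55 (camera adjusted p = 0.139). The most abundant member, hist2h2l, averaged 40.6 CPM over all libraries and was not called. Its log2 fold change was 0.07 for mutant against control in DMSO and 0.18 with palbociclib in mutant libraries. The other members averaged 8.86 CPM or less. h3c13a, among the 4 called lower, was at 19.7 CPM in mutant DMSO replicate 1 (others 5.95 to 8.47). hist2h3c was at 7.5 and 17.8 CPM in control and mutant libraries in DMSO and at 3.56 and 5.22 in palbociclib, and fell with palbociclib in mutant libraries (log2 fold change -1.78, SE 0.352, adjusted p = 0.00813).

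Of 15 eye and lens genes, 7 were called higher for mutant against control in DMSO (median 0.29, adjusted p = 0.00217; 0.363 with an estimated correlation) and 5 for palbociclib in control libraries (median 0.35, adjusted p = 5.76e-08; 0.123 with an estimated correlation). Of 12 genes of the nervous system, 6 and 5 were (medians 0.30 and 0.36, adjusted p = 0.00641 and 1.31e-06; 0.363 and 0.107 with an estimated correlation).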
